A study of Mus musculus with 15 samples.

How the data were processed

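Poly(A) RNA of a brain region dissected from 1 hemisphere of each mouse, after perfusion, was sequenced with a stranded library kit, per the labels' protocols; which region it was is not given in the sources used here. The values are raw read counts per gene, deposited by the authors as 1 table of 46078 Ensembl genes and 15 libraries. Per the submitters' processing notes, the tools were FastQC, Bowtie2 2.2.2, HTSeq 0.11.2 and DESeq2, with the mouse build GRCm38. Bowtie2 does not align across introns, so a read that spans an exon junction can be lost or misplaced, which lowers the counts of genes with many short exons and can favour processed pseudogenes. The annotation release, the strand setting and the other options are not given in the sources used here. The table ends with 5 HTSeq summary lines that name no gene. They were left out of library sizes and tests, and per library they stood for 19.966 to 25.854% of reads without a feature, 1.635 to 1.787% ambiguous and 2.699 to 2.917% not unique. An isotype antibody is named in the labels' treatment protocol; no library labelled with it was analysed here.

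Groups were taken from the labels (5 mice each), and the animal numbers in the labels make each library a separate mouse. No number is shared between groups, so no pairing was used. Within groups, the counts of each of the 30 pairs of libraries differed by more than sampling noise (chi-square per degree of freedom from 7.944 to 39.446), so no library was counted as a duplicate. Gene symbols matched 45143 of the identifiers, and the 935 without one held 0.101% of the counts. Places come from GENCODE M21, which uses the same build; its release may differ from the authors'.

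Values in CPM were computed here from the deposited counts with TMM scaling. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), on the 18974 genes kept by filterByExpr, with all 15 libraries in 1 model of group and labelled sex, which leaves 11 residual degrees of freedom. P values were adjusted by Benjamini and Hochberg's method, with a threshold of 0.05. Log2 fold changes are followed by standard errors derived from the F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the 39 lists; camera with an estimated correlation and fry were run beside it. With an estimated correlation no list passed an adjusted p of 0.05 in any of the 3 comparisons. Counts of list members are given over all genes tested and, where stated, adjusted over the list alone.

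Named genes followed a rule. In each comparison they were the 10 largest increases and the 10 largest decreases past the threshold with a mean of at least 1 CPM, or the 10 genes of smallest p where fewer than 5 passed, up to 4 members of smallest p from each list described, and Cd8a, Cd8b1, Cd3e, App, Prnp, Trem2, Cst7, Gfap, Arc, Xist and Ddx3y. A few genes that the rule takes are not reported here. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined. The fitted fold changes of Xist and Ddx3y are not given, because a sex label that goes against these genes enters the model. For Lamr1-ps1, at 0 in all WT libraries, the fold is a lower bound against 3 counts over the WT group.

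The tests were tried on simulated counts with 200 genes changed by known factors. Between APP-PS1 and WT mice given PBS, 14% of genes changed by a factor of 1.2, 54% at 1.5, 78% at 2 and 94% at 4 were recovered; between treated and PBS-given APP-PS1 mice the shares were 6%, 62%, 84% and 98%, and between treated and WT mice 8%, 60%, 80% and 92%. There were 2, 5 and 6 false calls, respectively. The simulated genes varied independently of each other, so these values leave out variation that genes share between libraries. Alternatives were DESeq2 1.42.0, limma-voom, other size factors, other filters, no sex covariate, covariates for the animal number series, for choroid plexus genes and for 1 surrogate variable (sva 3.50.0), the 2 groups alone, each sex alone, and leaving out each library in turn. The sex read from Xist and Y-linked genes, and leaving out the 5 libraries above 1000 CPM of Ttr, were added after the data were seen, except that the former was planned for the test of sex by treatment. Leaving out libraries of the group not compared, and splitting the WT libraries between both comparisons with them, were added as well.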

Results

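Gene expression was measured by RNA sequencing in brain tissue of 15 mice, each giving 1 library. The APP-PS1 mouse is a model of Alzheimer's disease that carries transgenes, among them a chimeric mouse and human amyloid precursor protein with the Swedish mutation, under a prion protein promoter that drives them in neurons. The groups were 5 wild-type (WT) mice given PBS, 5 APP-PS1 mice given PBS, and 5 APP-PS1 mice given an antibody against CD8a, a co-receptor on the surface of cytotoxic T cells. Mice were 12 months old at treatment, which lasted 4 weeks with 10 injections of 0.8 mg antibody each, or 100 µL of PBS. Counts assigned to genes ranged from 17736524 (APP-PS1 PBS replicate 5) to 36485809 (anti-CD8a replicate 5) per library. The group means were 30741454 ± 4849413 counts in WT mice, 26539787 ± 5861326 in APP-PS1 mice given PBS and 32148181 ± 3639202 in treated mice (SD, n = 5 each). At these depths 3 counts correspond to between 0.0822 and 0.169 CPM (counts scaled to the size of the library), a floor that covers counting error only.

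Tissue and sex markers differed between libraries. Ttr, the main transcript of the choroid plexus, was above 1000 CPM in 5 libraries. These were WT replicates 3 (2220 CPM) and 5 (6470 CPM), APP-PS1 PBS replicates 2 (4120 CPM) and 5 (1650 CPM) and anti-CD8a replicate 1 (1860 CPM), and the other libraries lay between 20.7 and 107 CPM. Xist, the RNA that silences an X chromosome in females, and the genes of the Y chromosome matched the labelled sex in 14 libraries. The library labelled APP-PS1 PBS replicate 1 is labelled male but had 1920 CPM of Xist and 2.08 CPM of Y-linked genes, the female pattern. By these genes the groups hold 4 females and 1 male (WT), 3 females and 2 males (APP-PS1 PBS) and 2 females and 3 males (anti-CD8a). The labelled sex was kept as the covariate of every test, and each count of genes past the threshold in a comparison was repeated with the sex read from the genes.

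**Figure D1:**
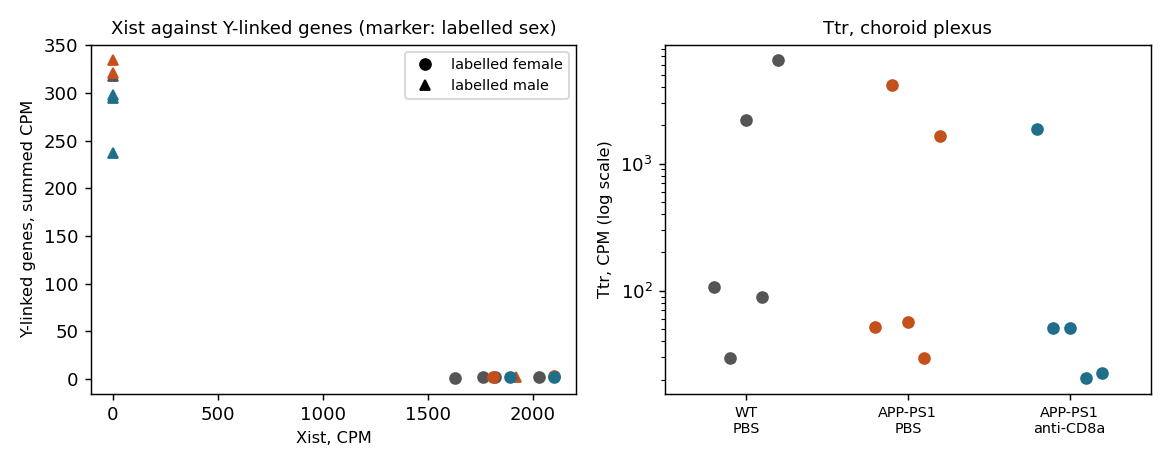
Left, summed CPM of Y-linked genes against CPM of Xist in each of the 15 libraries, with circles for mice labelled female and triangles for mice labelled male; grey is WT PBS, orange APP-PS1 PBS and blue APP-PS1 anti-CD8a. Right, CPM of Ttr per library on a log scale. The triangle at 1920 CPM of Xist is APP-PS1 PBS replicate 1, and 5 libraries lie above 1000 CPM of Ttr.

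The first comparison asked what the transgenes change in mice given PBS. Genes of microglia that gather around amyloid were among the most raised. Cst7, which encodes the protease inhibitor cystatin F, was at 19.3 ± 7.23 CPM in APP-PS1 mice against 0.35 ± 0.0849 CPM in WT mice (SD, n = 5 each), a log2 fold change of 6.17 (SE 0.40, adjusted p = 3.49e-07 in edgeR's quasi-likelihood test). Itgax, which encodes the integrin CD11c, rose by a log2 fold change of 4.34 (SE 0.37), and Clec7a, the receptor dectin-1, by 3.90 (SE 0.26). The chemokines Ccl3 (2.95) and Ccl6 (2.5), the receptor gene Ly9 (2.54) and the lysozyme gene Lyz2 (1.74) rose as well. Trem2, a lipid-sensing receptor of microglia, was 3.01-fold higher (30.1 ± 8.11 against 11.3 ± 0.327 CPM, adjusted p = 0.000445 in edgeR). In the list of disease-associated microglia all 29 tested members had a higher estimate in APP-PS1 mice, and 16 passed the test. The list passed camera (adjusted p = 1.35e-33, and adjusted p = 0.0622 with an estimated correlation).

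Other glial and immune genes rose too. In the list of homeostatic microglia 6 of 15 members passed, all upward, among them Fcrls (log2 fold change 0.99), Gpr34 (1.03) and Csf1r (0.59), the receptor that microglia need to survive. Of 19 complement genes 8 passed, led by C4b (1.25), C3ar1 (1.44), Itgb2 (0.98) and C1qa (0.97). Of 20 genes of reactive astrocytes 5 passed, including Osmr (1.03), Cd14 (1.31), Ggta1 (0.96) and Gfap, the intermediate filament of astrocytes, which was 2.34-fold higher (833 ± 172 against 383 ± 35.5 CPM). B2m (0.66) and H2-D1 (0.53) passed among 15 genes of MHC class I presentation. These 4 lists passed camera upward, with adjusted p values of 1.23e-15, 2.32e-09, 1.72e-10 and 2.79e-06, and with adjusted p values of 0.141, 0.147, 0.0672 and 0.263 with an estimated correlation. All 30 interferon response genes had a higher estimate and none passed singly, with a median log2 fold change of 0.48 (camera adjusted p = 1.23e-10, and adjusted p = 0.292 with an estimated correlation).

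**Figure D2:**
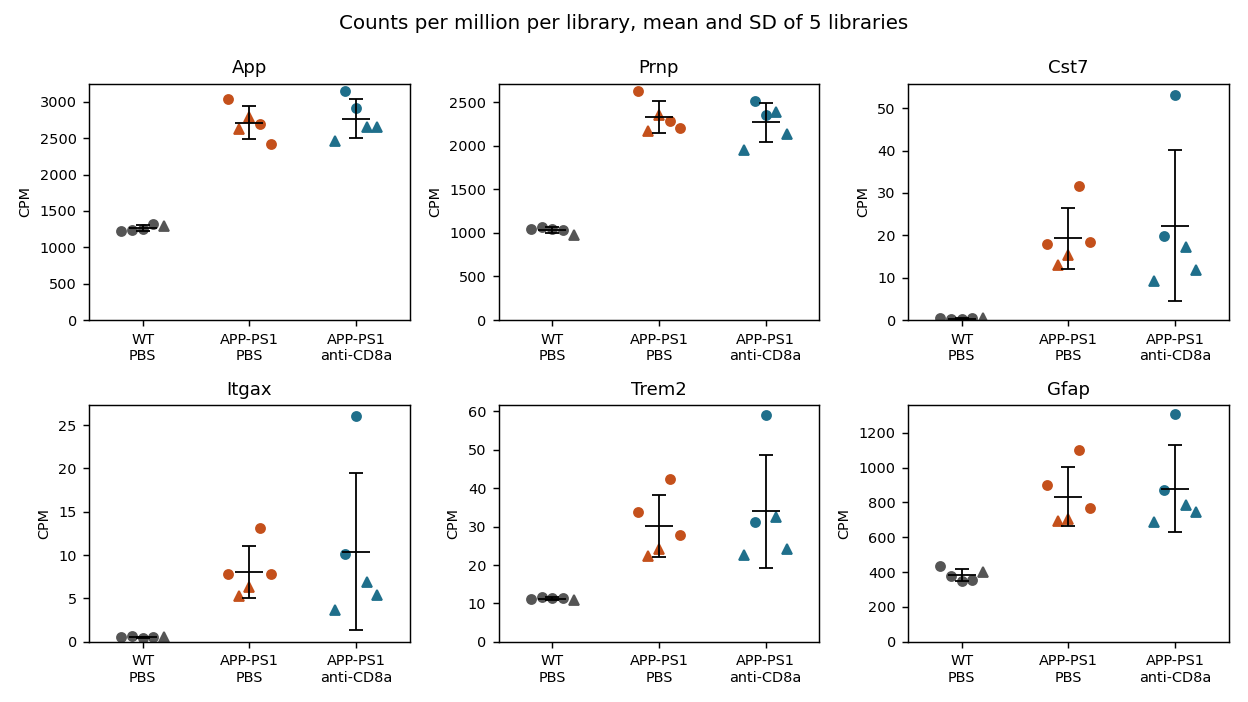
CPM of 6 genes in each library, by group (grey WT PBS, orange APP-PS1 PBS, blue APP-PS1 anti-CD8a). Circles are females and triangles males by Xist and Y-linked genes; the black marks are the mean and SD of 5 libraries. Cst7 averaged 0.35 CPM in WT mice, 19.3 CPM in APP-PS1 mice given PBS and 22.3 CPM in treated mice, where replicate 3 reached 53.2 CPM.

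Transcripts tied to the transgenes separated the genotypes in each library. App was 2.16-fold higher (2710 ± 226 against 1260 ± 40.6 CPM) and Prnp, whose promoter drives the transgenes, 2.29-fold higher (2330 ± 185 against 1030 ± 31.9 CPM). Lamr1-ps1, a processed pseudogene at chromosome 2 from 131904086 to 131904959 (GRCm38), 4.97 kb upstream of Prnp (131909928 to 131938429), was at 0 counts in the 5 WT libraries and at 50 to 134 counts in the 5 libraries of APP-PS1 mice given PBS. Against a floor of 3 counts over the WT group it was at least 200-fold higher. Reads of a processed pseudogene can be shared with its parent gene, although none were counted for it in WT mice.

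Fewer genes fell. Npy, a peptide of inhibitory neurons, had a log2 fold change of -0.49 (SE 0.07, 22.6 ± 1.96 against 32.4 ± 2.33 CPM, adjusted p = 0.00168 in edgeR). Crhbp (-0.47), Vgf (-0.50), which encodes a precursor of secreted neuropeptides, Egr3 (-0.54), an activity-induced transcription factor, and Ryr1 (-0.49), a calcium release channel, fell as well. The channel gene Ano2 (-1.39) and Gm20501 (-0.79), Lingo3 (-0.37) and Rhbdl3 (-0.34) were also among the 10 largest decreases; Gm20501 is a noncoding gene at a shared promoter, and the strand setting of the counting is not given in the sources used here. In the immediate early list 17 of 18 members had a lower estimate, with a median log2 fold change of -0.31, and Egr3 passed (camera adjusted p = 2.79e-06, and adjusted p = 0.292 with an estimated correlation). Arc, another member, had a log2 fold change of -0.56 (SE 0.23, adjusted p = 0.364 in edgeR). Of 18 genes of GABA signalling 13 had a lower estimate and Npy passed (camera adjusted p = 0.0137, and adjusted p = 0.292 with an estimated correlation). Hippocampal neuron markers had a median of -0.19 with none of 12 past the test (camera adjusted p = 0.00121, and adjusted p = 0.249 with an estimated correlation). All 10 striatal neuron markers had a lower estimate (median -0.23, camera adjusted p = 0.0378, and adjusted p = 0.169 with an estimated correlation). Of 28 postsynaptic genes 20 had a lower estimate and none passed, with a median of -0.09 (camera adjusted p = 0.00136, and adjusted p = 0.402 with an estimated correlation). The presynaptic and neuronal ion channel lists did not pass camera (adjusted p = 0.185 and 0.377), and the single presynaptic gene past the test, Rims1, was higher in APP-PS1 mice (log2 fold change 0.41, SE 0.07, adjusted p = 0.0103 in edgeR).

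Over all 18974 genes tested, 195 passed an adjusted p of 0.05 in edgeR, 178 higher and 17 lower in APP-PS1 mice, and 78 of them changed by more than 1 on the log2 scale. DESeq2 called 360 genes (280 higher, 80 lower), of which 194 were shared, and without the 5 libraries rich in choroid plexus the count was 98, all higher. Without APP-PS1 PBS replicate 4 the count was 253, with 119 lower.

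The comparison of treated with PBS-given APP-PS1 mice asked what the antibody changes in the transgenic brain, where the study's title places an effect of CD8-positive T cells on neuronal and synaptic genes. No gene passed the adjusted threshold in edgeR (smallest adjusted p = 0.223), 2529 of 18974 genes had an unadjusted p under 0.05 (1440 higher and 1089 lower in treated mice), and DESeq2 called 131 genes, 62 higher and 69 lower. The 10 genes of smallest p share that adjusted p of 0.223 in edgeR and are given as values. DESeq2 called all 10, with adjusted p values from 3.66e-05 (Npas4) to 0.00702 (Ampd2). At least 131 DESeq2 calls arose in 3 of 40 groupings of the same 10 libraries, the real one included. Npas4, a transcription factor induced by neuronal activity, was at 16 ± 2.67 CPM in treated against 8.29 ± 2.30 CPM in PBS-given mice (log2 fold change 0.95, SE 0.16). Ryr1 (0.51), Trpm4 (0.52) and Ampd2 (0.26) also had higher estimates. The axon guidance gene Sema3d had a log2 fold change of -0.66 (SE 0.11, 12.6 ± 1.13 against 19.9 ± 3.55 CPM), and estimates were lower for Tpbg (-0.96), Dlk1 (-1.17), Rtp1 (-1.79), Arhgap6 (-0.68) and Tmem255a (-0.40).

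**Figure D3:**
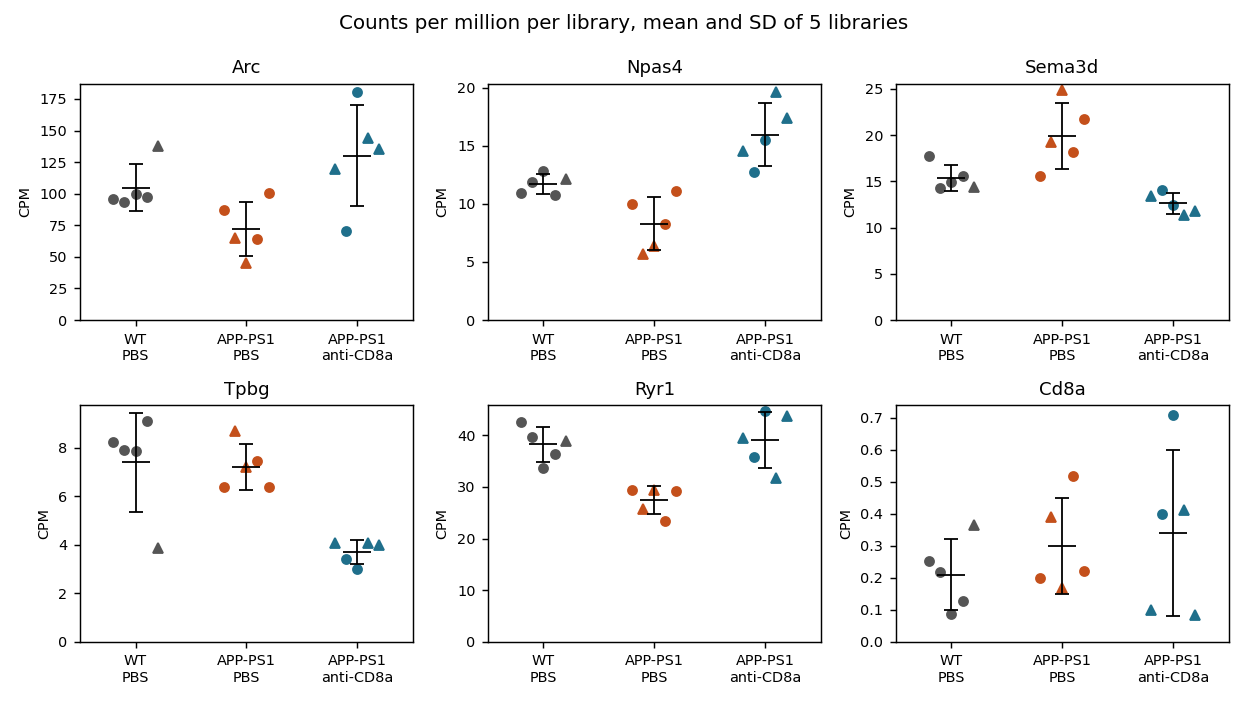
CPM of 6 genes per library, by group (grey WT PBS, orange APP-PS1 PBS, blue APP-PS1 anti-CD8a), with circles for females and triangles for males by Xist and Y-linked genes and black marks for the mean and SD of 5 libraries. Arc averaged 72.2 CPM in APP-PS1 mice given PBS and 130 CPM in treated mice, and Cd8a averaged 0.299 and 0.34 CPM. None of the 6 passed the edgeR threshold between these groups, and DESeq2 called Npas4, Sema3d, Tpbg and Ryr1.

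Neuronal activity genes had the smallest camera p of the 39 lists in this comparison with the preset correlation. All 18 immediate early genes had a higher estimate in treated mice (median log2 fold change 0.62). In edgeR 16 passed when adjusted over the list alone, against none over all genes tested. Egr1 had a log2 fold change of 0.64. Nr4a1 was at 56.3 against 35.6 CPM (0.67), Egr4 at 5.38 against 2.88 CPM (0.88) and Arc at 130 ± 40 against 72.2 ± 21.5 CPM (0.85, SE 0.22). The list passed camera (adjusted p = 4.13e-10, and adjusted p = 0.368 with an estimated correlation). Hippocampal neuron markers moved with it: all 12 had a higher estimate, with a median of 0.27, and 7 passed adjusted over the list alone (camera adjusted p = 7.03e-05, and adjusted p = 0.368 with an estimated correlation). Among 28 postsynaptic genes 5 passed adjusted over the list alone, and the kinase genes Camk2b (0.30) and Camk2a (0.25), the scaffold gene Shank3 (0.32) and the receptor gene Grin1 (0.19) had the smallest p (camera adjusted p = 0.00155, and adjusted p = 0.78 with an estimated correlation). The presynaptic, neuronal ion channel and GABA signalling lists did not pass camera (adjusted p = 0.0747, 0.0799 and 0.192). None of their members passed adjusted over the list alone. DESeq2 called 2 immediate early genes (Npas4 and Egr4), 3 hippocampal markers (Lct, Cabp7 and Tdo2) and 3 postsynaptic genes (Camk2b, Shank3 and Camk2a).

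Interferon and MHC class I genes had higher estimates in treated mice, and glucocorticoid-induced genes lower ones. All 30 interferon response genes were on the higher side (median 0.46), led by Rtp4 (0.86), Isg15 (0.80), Irf7 (0.97) and Irf9 (0.43). In edgeR 14 were past the threshold adjusted over the list alone and none over all genes. DESeq2 called 2 of the 30, Rtp4 and Irf7. Of 15 MHC class I genes 14 were higher, with Tap1 (0.41) and Tap2 (0.26) at the smallest p. Camera gave adjusted p values of 5.52e-09 and 0.000218 for the 2 lists, and adjusted p values of 0.713 and 0.702 with an estimated correlation. All 10 glucocorticoid response genes had a lower estimate (median -0.48), 5 of them past the threshold adjusted over the list alone, with Sgk1 at 113 against 183 CPM (-0.72), Tsc22d3 at 74.4 against 114 CPM (-0.64) and Plin4 at 13.4 against 34.0 CPM (-1.47). That list had a camera adjusted p of 1.33e-06, and an adjusted p of 0.477 with an estimated correlation. DESeq2 called 1 of its members, Sgk1. Choroid plexus markers differed alongside these groups, with a median of -1.86 over 14 genes and none past the test. Markers of the cerebellum (7 of 7 lower estimates, median -0.84), mural cells and fibroblasts (13 of 16 lower, -0.51) and ependymal cells (8 of 8 lower, -0.49) had lower estimates as well, again with none past the test over all genes. Their camera adjusted p values were 0.00332, 0.0125 and 0.0131, and that of the choroid plexus list 0.0131, with adjusted p values of 0.368, 0.833, 0.833 and 0.833 with an estimated correlation. The list of disease-associated microglia had a median of 0.03, with no member past the threshold over all genes (camera adjusted p = 0.863, with the opposite sign to the median). Adjusted over the list alone 1 member passed, Timp2, an inhibitor of metalloproteases, which had a lower estimate (-0.40, SE 0.10) and was called by DESeq2. Cst7 (0.07, SE 0.26), Trem2 (0.14, SE 0.18) and Gfap (0.06, SE 0.14) had standard errors larger than their estimates.

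**Figure D4:**
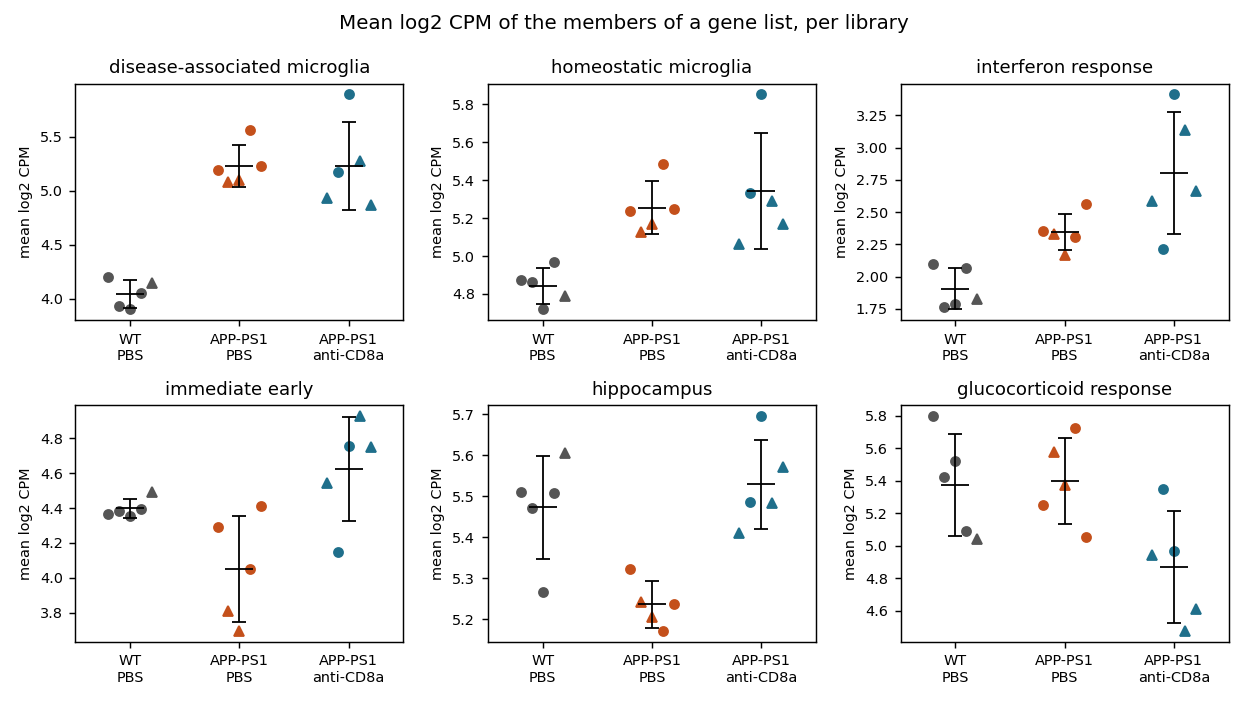
Mean log2 CPM of the members of 6 gene lists in each library, by group (grey WT PBS, orange APP-PS1 PBS, blue APP-PS1 anti-CD8a), with circles for females and triangles for males by Xist and Y-linked genes and black marks for the mean and SD of 5 libraries; the axes do not start at 0. The median log2 fold change between treated and PBS-given APP-PS1 mice was 0.62 for the immediate early, 0.46 for the interferon and -0.48 for the glucocorticoid list.

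Transcripts of Cd8a, Cd8b1 and Cd3e were near the floor in all groups. Cd8a, the target of the antibody, had 33 counts over the 5 WT libraries, 42 over the 5 APP-PS1 PBS libraries and 53 over the 5 treated libraries (0.21 ± 0.11, 0.299 ± 0.15 and 0.34 ± 0.259 CPM, n = 5 each). Its log2 fold change between treated and PBS-given APP-PS1 mice was 0.07 with an SE of 0.51. Its counts were thus no lower in treated mice, but with this SE and so few counts a sizeable loss could have gone undetected. Cd8b1 had 9, 13 and 14 counts and Cd3e 11, 22 and 22 counts in the same order, and both were below the filter for testing.

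Treated APP-PS1 mice were also compared with WT mice given PBS, which joins genotype and treatment. Lamr1-ps1 was at least 167-fold higher against the same floor. The microglial genes were again among the largest increases, with Cst7 at a log2 fold change of 6.24 (SE 0.39), Itgax at 4.52, Clec7a at 3.76 and Ccl3 at 3.29, and 17 of 29 disease-associated microglia genes passed upward (camera adjusted p = 3.17e-31, and adjusted p = 0.0525 with an estimated correlation). Of the interferon response genes 19 of 30 passed upward, among them Trim30a (1.15, SE 0.18), Oasl2 (1.51), Rsad2 (1.09) and Irf7 (1.55), and the median of the list was 1.02 (camera adjusted p = 2.28e-28, and adjusted p = 0.0852 with an estimated correlation). Without anti-CD8a replicate 3 only 1 interferon gene passed. Ifi204, an interferon-induced gene outside that list, had a log2 fold change of 2.16 (SE 0.33, adjusted p = 0.00188 in edgeR). The MHC class I list had 6 of 15 members past the test, with H2-D1 (0.73), B2m (0.71), H2-Q4 (0.59) and Psmb8 (0.83), and the homeostatic microglia list 10 of 15, with Cx3cr1 (0.82), Fcrls (1.05) and Csf1r (0.73); camera adjusted p values were 9.43e-15 and 4.67e-19, and adjusted p values 0.0605 and 0.0669 with an estimated correlation.

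Genes lower in treated APP-PS1 than in WT mice included the neuropeptide gene Npy (-0.45), the imprinted genes Dlk1 (-1.36) and Magel2 (-1.12), the neuronal globin gene Ngb (-1.03), the receptor gene Gpr101 (-0.98), Rtp1 (-1.64), which encodes a chaperone of odorant receptors, and Xlr3b (-2.30), Ecel1 (-1.50) and Arhgap6 (-1.05). Choroid plexus markers had a median of -2.37 in the same comparison with none of 14 past the test. The immediate early and postsynaptic lists did not pass camera in this comparison (adjusted p = 0.0947 and 0.892), with medians of 0.22 and -0.004. In all, 369 of 18974 genes passed in edgeR, 334 higher and 35 lower. The count was 140 without anti-CD8a replicate 3 and 199 without the 5 libraries rich in choroid plexus.

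Both comparisons with WT mice shared 157 of the genes called higher and 7 of those called lower, against 3.13 and 0.03 for independent lists, and against 0 in 20 simulations of unchanged groups that share the WT libraries. Those simulations called 0.05 and 0.1 genes per comparison on average, so they do not show how sharing affects lists of this size. With the WT libraries split between both comparisons, which leaves fewer mice in each, 71.2 and 133 genes were called higher on average over 20 splits, and 44 were shared (20 to 69, against 0.40 for independent lists). Of the genes called lower 1 was shared on average (0 to 3). Another 177 genes were called higher against WT in treated but not in PBS-given mice; as no gene passed between those groups in edgeR, this does not show that the effects differ. Across the 18974 genes, which are not independent replicates, the genotype effect and the treatment effect had a Pearson correlation of -0.278 (jackknife SE 0.222 over the 15 libraries) and a covariance of -0.0159. The APP-PS1 PBS libraries enter both effects with opposite sign, and simulated unchanged groups gave a correlation of -0.494 (SD 0.015 over 100 simulations) and a covariance of -0.0190, which is 0.0031 below the observed one. Genes varied independently in these simulations as well, so the SD of 0.015 leaves out variation that genes share. With the APP-PS1 PBS libraries split between the effects, the correlation averaged 0.067 over 20 splits (-0.114 to 0.407).

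The treatment effect was also compared between the sexes in the 10 APP-PS1 libraries, by labelled sex. No gene passed in edgeR's interaction test, 715 had an unadjusted p under 0.05, and DESeq2 called 5, named after their values were seen (mt-Nd1, mt-Nd2, Lars2, Rpph1 and Hbb-bs), each with a higher treatment effect in males. The labelled sex of APP-PS1 PBS replicate 1 went against its transcripts, and with the sex read from the genes 0 genes passed in edgeR as well, with 647 at an unadjusted p under 0.05. DESeq2's interaction test was not repeated with that sex, so its 5 calls rest on the labelled sex.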

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

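The test of 1 treated library behind the interferon genes was chosen after the result was seen. So were the splits of the interferon list in comparisons other than treated against WT mice. The other tests in this part were set before. Within each group of 5 libraries, a library whose gap to its nearest neighbour took up most of the group's range was marked (Dixon's 95% limit), which chance does in about 1 of 20 groups. Of 246 groups of values, 29 were marked (11.8%).

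Anti-CD8a replicate 3 stood apart in microglial genes, with 53.18 CPM of Cst7 (the other treated libraries had 9.313 to 19.75), 26 CPM of Itgax, 18.66 CPM of Ccl6 and 59.17 CPM of Trem2. The same library had the lowest treated values of Vgf (42.94 CPM) and Magel2 (0.8082 CPM) and the highest mean of the oligodendrocyte precursor list (5.683 log2 CPM). Anti-CD8a replicate 4 had a thalamus list mean of 5.395 log2 CPM (the other treated libraries had 3.354 to 3.661), an ependymal list mean of -0.26 and 2.581 CPM of Xlr3b. Anti-CD8a replicate 1 had a choroid plexus list mean of 4.797 log2 CPM and 2.003 CPM of Gm20501.

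Among APP-PS1 mice given PBS, replicate 4 had 31.63 CPM of Cst7 and 4.453 CPM of Ly9, replicate 5 had 2.043 CPM of Magel2, and replicate 2 had a striatum list mean of 3.187 log2 CPM. Replicate 1, whose sex label goes against its transcripts, had an endothelial list mean of 4.405 and a mural and fibroblast list mean of 3.313 log2 CPM, below the others.

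WT replicate 5, the male of its group, had 2.869 CPM of Xist, 114.6 CPM of Ddx3y and a sex list mean of 4.25 log2 CPM. It also stood apart in Arc (138.1 CPM), Tpbg (3.881 CPM), the immediate early list (4.491 log2 CPM), the neurogenesis and cell cycle list (2.4) and the heat shock list (6.035). WT replicate 1 stood apart in Ifi204 (1.486 CPM) and the astrocyte list (8.184 log2 CPM), and WT replicate 2 in the thalamus list (3.277).

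The interferon list was higher in treated APP-PS1 than in WT mice, with a median log2 fold change of 1.02. As large a median in either direction arose in 2 of 60 splits of the same 10 libraries, the real one included, with 1.18 as the highest of the others, so a chance arrangement of mice is an unlikely source. Leaving out 1 treated library lowered the median to 0.78 at the least, which argues against a single mouse as the source of the median, although the count of members past the threshold fell from 19 to 1 without anti-CD8a replicate 3. With the mean of the homeostatic microglia list as a covariate the median was 0.12 (-0.10 to 0.58 on leaving out each library), so more microglial RNA cannot be told apart from a change in interferon signalling, since that list itself was higher in treated than in WT mice. The transgenes and the antibody, which this comparison joins, stay open as biological sources. The list median was 0.48 between PBS-given APP-PS1 and WT mice, reached in 1 of 60 splits (highest other 0.38). Between treated and PBS-given APP-PS1 mice it was 0.46, reached in 9 of 60 (highest other 0.61), so chance is not excluded for that part either.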

How the results depend on the processing

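The alternatives with the sex read from the genes (except for sex by treatment), without choroid-rich libraries or without a library of the group not compared were added after the data were seen. The count of 195 genes between APP-PS1 and WT mice given PBS stayed within 1.5 times under the other size factors, filters and covariates, limma-voom and the sex read from the genes (181 to 268). It was 360 with DESeq2, 115 without the sex covariate, 98 without the choroid-rich libraries, 86 in females and 2 in males by label, and 109 and 1 by the sex read from the genes. Leaving out each library gave 145 to 253.

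Between treated and PBS-given APP-PS1 mice the count of 0 in edgeR became 131 with DESeq2, 13 without the low-count filter (Npas4, Ryr1 and Rnf213 higher), 1 with only the 2 groups (Tpbg) and 1 in females by either sex (Gpr101), and 0 to 3 on leaving out each library (3 without WT replicate 5, and at most 2 without a library of the groups compared). It was 0 with limma-voom, other size factors, at least 1 CPM in 5 libraries, each covariate and in males. Between treated and WT mice the count of 369 became 221 with only the 2 groups, 199 without the choroid-rich libraries, and 1 in males by either sex. Leaving out each library gave 140 (without anti-CD8a replicate 3) to 441. The sex by treatment count of 0 became 5 with DESeq2 and 97 without the filter, and 0 to 3 on leaving out each library. Tests within 1 sex use fewer mice, and those of males against WT mice rest on 1 WT male (replicate 5), assumed to vary like the other groups, so they say little about males; the cause of the other changes was not tested.

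Camera's counts of 18, 11 and 18 lists became 0, 0 and 0 with an estimated correlation, and 8, 0 and 12 with fry; leaving out each library of the groups compared gave 13 to 21, 9 to 17 (without anti-CD8a replicate 3) and 17 to 20. The correlation of the genotype and treatment effects (-0.278) reversed to 0.067 with the APP-PS1 PBS libraries split, because these libraries are then not shared, and lay between -0.391 and -0.172 on leaving out each library. Of 24 called genes named against WT mice in each comparison, 13 (genotype) and 14 (treated) kept their call in every alternative checked for them except those within 1 sex. Leaving out a library of the group not compared was not checked for these genes. Gpr101 changed sign against that single WT male (0.19 by label and 0.19 by the genes, against -0.98 with all mice), which is no test of a sex difference. Genes near the floor, such as Cd8a, are limited by depth.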

Other observations

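The test of transgene RNA behind Lamr1-ps1 was chosen after the result was seen. So were the splits for single lists, except the immediate early list between treated and PBS-given APP-PS1 mice and the disease-associated microglia list. The other tests in this part were set before. Some gene groups outside the report differed between genotypes in camera with the preset correlation. Of 30 nuclear genes of oxidative phosphorylation all had a lower estimate in APP-PS1 than in WT mice given PBS (median log2 fold change -0.12, camera adjusted p = 3.68e-08, and adjusted p = 0.353 with an estimated correlation), while 9 of 9 tested mitochondrially encoded genes had a higher one (median 0.32, camera adjusted p = 0.0257, and adjusted p = 0.443 with an estimated correlation). No gene of either list passed singly. Mitochondrially encoded genes held a mean of only 0.128% of the counts in APP-PS1 mice given PBS and 0.116% in WT mice, and 9 of 13 listed were tested. Why this share is so small was not examined, so their values are a weak measure of mitochondrial transcription. Cholesterol synthesis genes, led by Fdft1 (0.24) and Msmo1 (0.21), had 14 of 16 higher estimates (camera adjusted p = 0.000199, and adjusted p = 0.392 with an estimated correlation). Medians as large arose in 4, 7 and 10 of 60 splits for these 3 lists, so chance is not excluded. Aqp4, the water channel of astrocyte endfeet, rose by a log2 fold change of 0.46 (SE 0.10, adjusted p = 0.0459 in edgeR). The T cell list had 14 of 31 members tested, and Pdcd1, which encodes the checkpoint receptor PD-1, was at 0.786 ± 0.546 CPM in treated APP-PS1 mice, 0.484 ± 0.221 in PBS-given ones and 0.104 ± 0.0654 in WT mice, where it is at the floor (SD, n = 5 each). In edgeR its adjusted p was 0.00817 between treated and WT mice, 0.0912 between PBS-given APP-PS1 and WT mice, and 0.506 between treated and PBS-given APP-PS1 mice.

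Splits of the same 10 libraries into other groups of 5 show which counts exceed chance. Between APP-PS1 and WT mice given PBS, 1 of 60 splits, the real one, reached 195 genes, and the highest other had 3; between treated and WT mice 1 of 60 reached 369, and the highest other had 122. Chance is excluded at this level for both. Between treated and PBS-given APP-PS1 mice, 5 of 60 splits had at least 2529 genes under an unadjusted p of 0.05 (highest other 3367), and 3 of 40 had at least 131 genes in DESeq2 (highest other 305), so chance is not excluded for either. Between APP-PS1 and WT mice given PBS, 5 of 60 splits likewise reached the unadjusted count of 2173 genes (highest other 3071). The unadjusted count therefore does not set these 2 comparisons apart. The split with 3367 genes exchanged APP-PS1 PBS replicate 1 and anti-CD8a replicate 4, and it called 84 genes at the adjusted threshold against 0 in the real split. The cause was not tested. Replicate 1 is the library whose sex label goes against its transcripts. Every split used the labelled sex, and none was repeated with the sex read from the genes. With that sex the real groups of this comparison had 2964 genes under an unadjusted p of 0.05 in edgeR. The split results thus hold for the labelled sex only. Counts of lists called by camera were as large in 9 of 60 splits (genotype, 18 lists, highest other 23), 27 of 60 (treatment, 11 lists, highest other 17) and 8 of 60 (treated against WT, 18 lists, highest other 22), so these counts are not above chance. The median of the disease-associated microglia list between APP-PS1 and WT mice given PBS (0.88) was reached in 1 of 60 splits, with 0.75 as the highest other. In the same comparison the homeostatic microglia, interferon, reactive astrocyte and striatum medians were each reached in 1 of 60 splits. The immediate early median was reached in 2. Those of complement and hippocampus genes were reached in 4, MHC class I in 7, GABA signalling in 8 and postsynaptic in 9. Chance is not excluded for lists reached in 4 or more splits, and no allowance was made for the 39 lists. Between treated and PBS-given APP-PS1 mice, the medians of the postsynaptic (0.15) and hippocampus (0.27) lists were each reached in 1 of 60 splits, with 0.13 and 0.27 as the highest others, out of 39 lists. Medians of other lists described in that comparison were reached more often: cerebellum in 2 (highest other 1.00), glucocorticoid response in 3 (0.58), MHC class I in 7 (0.29), interferon response in 9 (0.61), mural and fibroblast in 11 (0.90), ependymal in 15 (0.87) and choroid plexus in 19 of 60 splits (4.07).

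The immediate early genes were higher in treated than in PBS-given APP-PS1 mice, with a median log2 fold change of 0.62. As large a median arose in 4 of 60 splits (highest other 0.75), so a chance arrangement is not excluded. With the choroid plexus covariate the median was 0.56 (0.41 to 0.73 on leaving out each library), which argues against choroid tissue. Of 12 clock genes 2 had an unadjusted p under 0.05, Per1 higher (0.23) and Npas2 lower (-0.31), against 13.33% of all genes tested. This count was below the bound set before for the time of day. That bound ignores direction and the share over all genes, so a difference in the time of day is not excluded. With the mean of the hippocampus list as a covariate the median was 0.29 (0.24 to 0.47 on leaving out each library), so a larger share of hippocampal neurons in the dissected tissue cannot be told apart from a change in activity, because these values lie on both sides of the bound set before. Treatment, handling and the lower glucocorticoid genes stay open, and none of them was tested separately. Heat shock genes, listed as raised by stress or handling, had 9 of 10 lower estimates in treated mice (median -0.10). Their camera adjusted p was 0.00507, and 0.702 with an estimated correlation, and as large a median arose in 7 of 60 splits.

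Lamr1-ps1 and Prnp reads were found in every APP-PS1 library. A rise of the whole region is argued against by 12 tested genes within 500 kb of Prnp, whose median log2 fold change was 0.00 (-0.34 to 0.25). RNA from a transgene vector that carries the prion promoter region with this pseudogene stays open: the lowest count in the 10 APP-PS1 libraries was 50 and the highest in the WT libraries was 0, but this restates the observation and could not count for that explanation. The vector's sequence was not used here. Genes called between APP-PS1 and WT mice given PBS showed no excess on a chromosome (smallest adjusted p 0.568 over 20 chromosomes, on chromosome 11, Fisher's exact test), but a count per chromosome cannot show a few genes linked to an insertion site.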
